A study of Mus musculus with 2 samples.

How the data were processed

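The material was whole liver of healthy adult mice, immunoprecipitated with an antibody against GATA4 and sequenced, with 2 samples in 1 group. Per the labels the samples are biological replicates 1 and 2, and both carry the same biosample and donor identifiers. Nothing else in the labels says that they came from separate animals, so values that differ between them show a spread that may be technical. Sex and age of the donor are not given in the sources used here.

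Peak lists from 15 deposited files were used, of which 13 are on the genome build mm10 and 2 archived ones on mm9. Per the file headers and the README tables deposited with the samples, the mm10 lists come from an earlier and a later run of the authors' processing. The earlier run gave a relaxed list per replicate and one for the pooled reads, the optimal list and a conservative list. In it each replicate's relaxed list used a control file of its own and the pooled list used both. The later run gave ranked and thresholded lists for each replicate and for the pooled reads, and a second conservative list, each with both control files. The main set is therefore from the earlier run and the replicates' own thresholded lists are from the later one. The aligner and the peak caller of the mm10 lists are not given in the sources used here. The line names of the mm9 lists name MACS2 and SPP. Those lists were neither converted nor compared with the mm10 lists.

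The irreproducible discovery rate (IDR) score deposited with each peak is 125 times the negative log2 of the IDR, capped at 1000, as read from the values. The thresholded lists hold peaks with an IDR score of at least 540 (later run) or 537 (earlier run), and 540 is an IDR of 0.05. The peak caller's signal score was deposited without a unit. This score was used only to rank and describe peaks within 1 list. Ranked lists also hold the signal score of both inputs, deposited in columns of their own. In the list ranked between the replicates, 85.3% of the thresholded first positions were found in replicate 1's own ranked list and 99.7% of the second in replicate 2's. Read depth is not in these files and is unknown, so no interval for reads was computed.

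Coordinates were set against the GRCm38.p6 sequence, which is mm10, and GENCODE mouse release 21 basic genes. No peak lay past the end of a chromosome. There were 21938 protein-coding genes with 41492 distinct transcription start sites. Peaks outside chromosomes 1 to 19, X and Y, 33 in the optimal list, were left out. The optimal list repeats a position in 12 lines, each with its own summit, and these lines were kept. Coordinates are printed from 1.

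A summit within 1 kb of a start site was called promoter, and otherwise exon, intron or intergenic. Shares were set against 100 shuffles of the list within chromosomes outside assembly gaps. Motifs were searched on both strands within 50 bp of the summit and in windows of the same length 500 bp to each side, with a two-sided Fisher's exact test and the Benjamini-Hochberg correction over 19 motifs. Windows are not replicates. Overlap between lists meant at least 1 shared base. For each of 18 gene lists, the number of members with a summit in the gene or within 10 kb was compared with 10000 random lists of the same size drawn in 20 bins of gene span, a permutation of list membership within bins. Promoter and other peaks were also compared at like GC, in bins of 5 points weighted to the promoter peaks and with at least 20 other peaks each. Intervals of these gaps came from 1000 bootstrap resamples of peaks. Genes of chromosome Y were left out, which left 21755. Anxa13, of the cholangiocyte list, was not found in the annotation and was left out.

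The gene lists and the rule for named genes were fixed before the data were examined. The text names every GATA and FOG gene, at most 6 members of each other list by the rank of their strongest peak, and the 10 strongest peaks overall and at promoters. Some items that this rule names are not reported here. Alternatives were other definitions of overlap, a stricter IDR of 0.01, lists of other lengths, the conservative list, the strongest quintile, promoters within 2.5 kb, AGATAA in place of WGATAR, windows of 100 bp, flanks at 2000 bp, other links between peaks and genes, random lists without matching, and each replicate's own list in place of the optimal one. Settings with promoter peaks alone or without them, the later run's thresholded list and an equal length of 26314 were added after seeing the data.

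The overlap, motif, gene-list, GC-matching, per-gene permutation and rank correlation code was tested on simulated data. An overlap planted in 40% of 4287 peaks was recovered at 40.4%, and a motif planted to a share of 44.3% of 5000 windows at 44.4%. Of 200 random gene lists 4% fell below 0.05, and of 50 lists with most members near a peak 100% did. A GC-matched gap made with 0 points came out at 0.23 and one of 10 points at 10.22, over the 24050 summits. The motif was drawn from GC there, so an effect of the motif on GC was not simulated. Permutations over genes fell below 0.05 in 5.5% of 200 runs without a difference. The repeat share and the other bootstrap intervals were not simulated. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.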

Results

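Binding of the transcription factor GATA4 was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole liver of healthy adult mice. GATA4 is a zinc-finger protein that recognises the DNA sequence WGATAR, where W is A or T and R is A or G. The series held 1 group with 2 samples, labelled as biological replicates 1 and 2. Both samples carried the same tissue and donor identifiers in the labels, so the spread between them may be technical. There was no treated group, and the control libraries that the labels point to were not used here. The design therefore implied comparisons between the replicates, between peaks and their flanking sequence, and between gene groups. Peak lists were used, and the sequencing depth behind them is unknown. Replicate 1 had 4287 peaks past the authors' reproducibility threshold and replicate 2 had 26314. The authors' optimal list, made from both replicates, held 24083 peaks on the mouse genome build mm10, of which 24050 lay on the assembled nuclear chromosomes and were analysed. Their conservative list held 9251 peaks. In the later run, 10018 peaks passed the threshold in the list ranked between the replicates and 23797 in the pooled ranked list. A peak of the optimal list is thus not necessarily in both replicates' lists. All percentages below have 95% Wilson intervals where intervals are given, and these cover counting error over peaks only. Peaks, windows and genes are not replicates, so each p-value describes these lists.

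The optimal list placed GATA4 near genes of the liver sinusoidal endothelium and of hepatocyte metabolism, and also near the ubiquitous genes fixed as a background list (18 of 20, against a mean of 8.73 in random lists). Of 18 gene lists fixed before the data were examined, 9 had more members with a peak summit in the gene or within 10 kb than random lists of the same size and gene span. The random lists were matched on gene span only. Among 21755 protein-coding genes, 47.6% had such a summit. A summit within this distance does not assign the peak to the gene, and neighbouring genes can share a peak. The adjusted permutation p-values below are one-sided shares of 10000 random reassignments of list membership within bins of gene span, corrected by the Benjamini-Hochberg method over the 18 lists.

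The list of liver sinusoidal endothelial cells, the fenestrated lining of the liver's capillaries, had a summit near 28 of 29 genes, against a mean of 15.8 in random lists (adjusted permutation p = 0.00036, from the smallest share that the random lists can give). Replicate 1's own list reached 18 of these genes and replicate 2's 28. The strongest peak of this list lay on chromosome 10 at 127756090 to 127756435, upstream of Gpr182, an endothelial receptor gene, and ranked 29 in the optimal list. Peaks of high rank also lay upstream of Oit3 (rank 60), in an intron of the mannose receptor gene Mrc1 (rank 85) and in an intron of Flt1, which encodes a receptor for vascular endothelial growth factor (rank 133). The promoter of Tek, which encodes the angiopoietin receptor, carried the peak of rank 144, and a region upstream of Egfl7 that of rank 214. The peaks of these 6 genes were in both replicates' lists. Rspo3 was the 1 member without a summit, and was named after the values were seen.

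Hepatocyte genes had a summit near 24 of 30 members, against a mean of 13.7 in random lists (adjusted permutation p = 0.0006). Replicate 1's list reached 10 of them and replicate 2's 26. The peak of rank 15 lay on chromosome 16 at 22881492 to 22881782, upstream of Ahsg, which encodes the plasma protein fetuin-A. Apoa2, an apolipoprotein gene, had a peak 1065 bp from its transcription start site (rank 406), and this peak was also the strongest one near Nr1i3. An intron of Slc2a2, the hepatocyte glucose transporter gene, held the peak of rank 496. The strongest peaks near Cebpa, Hnf4a and Alb ranked 1233, 1443 and 2230.

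Genes of liver transcription factors had a summit near 23 of 24 members, against a mean of 12.3 (adjusted permutation p = 0.00036), with 13 in replicate 1's list and 22 in replicate 2's. An intron of Ppara, which encodes a fatty acid receptor, held the peak of rank 38, on chromosome 15 at 85774444 to 85774759. Peaks also lay upstream of Cebpb (rank 164), at a promoter of Nr5a2 (rank 270), in an intron of the xenobiotic receptor gene Nr1i2 (rank 436) and downstream of Nr0b2 (rank 556), a corepressor gene of bile acid synthesis.

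The metabolic lists gave a like result. Glucose and fasting metabolism had a summit near 18 of 20 genes (adjusted permutation p = 0.001), with 12 in replicate 1's list and 19 in replicate 2's. Its strongest peaks lay upstream of Angptl4 (rank 107), an inhibitor of lipoprotein lipase, and of G6pc (rank 388), which encodes the catalytic subunit of glucose-6-phosphatase. Introns of Creb3l3, Ppargc1a and Insr held peaks of rank 524, 590 and 769. Bile acid and sterol genes had a summit near 16 of 20 members (adjusted permutation p = 0.015), with 9 in replicate 1's list and 17 in replicate 2's. Their strongest peak, of rank 99, lay on chromosome 17 at 84682895 to 84683170 between the divergent promoters of Abcg5 and Abcg8, which encode a sterol transporter, and had 3 copies of WGATAR within 50 bp of its summit. Scarb1, a lipoprotein receptor gene, had 9 peaks, and Cyp7a1, the gene of the rate-limiting enzyme of bile acid synthesis, had 2. Urea cycle and amino acid catabolism had a summit near 17 of 18 genes (adjusted permutation p = 0.00036), with 7 in replicate 1's list and 18 in replicate 2's, the strongest at the promoter of Got1 (rank 48). Cytochrome P450 and conjugation genes had a summit near 16 of 20 members (adjusted permutation p = 0.0079), the strongest at a promoter of Por (rank 206), which encodes the electron donor of these enzymes. Replicate 1's list reached 7 of them and replicate 2's 17. With summits within 5 kb of a start site 11 of 20 had one, which missed the threshold (adjusted permutation p = 0.0576). The mean of random lists was 6.41 there, against 9.67 in the main run. Peaks lay upstream of Cyp2j5 (rank 622), Cyp3a11 (rank 919) and Cyp4a10 (rank 1699). Heme and iron genes had a summit near 19 of 20 members (adjusted permutation p = 0.00036), led by the promoter of Cpox (rank 123) and a site downstream of the iron exporter gene Slc40a1 (rank 131). With replicate 1's shorter list alone, heme and iron had 5 of 20 genes and missed the threshold (adjusted permutation p = 0.054). The mean of random lists fell as well, from 8.93 with the optimal list to 1.77.

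The 9 lists that missed the threshold did so in a one-sided test, which asks only for high counts. Of the Kupffer cell and macrophage genes 5 of 20 had a summit, below the central 95% of random lists (6 to 14), and 0.57% of random lists fell below this count. The count lay inside the central 95% with summits within 5 kb of a start site (4, range 3 to 11), random lists without matching (5, range 5 to 14), the conservative list (3, range 1 to 8) and replicate 1's list (2, range 0 to 5). It also lay inside with summits outside promoters (3, range 3 to 10) and with those of them that had WGATAR (3, range 1 to 8). It stayed below by nearest start site (3, range 4 to 12), with replicate 2's list (5, range 7 to 15) and with the later run's list (4, range 6 to 14). So the low count depends on the setting. The hepatic stellate cell and mesenchyme list had 9 of 25, the cholangiocyte list 4 of 14 and the lymphocyte list 6 of 15, each inside the central 95% of random lists. The strongest peak of the stellate list lay in an intron of Bmp10 (rank 3343), and that of the lymphocyte list downstream of Cd79a at a promoter of Arhgef1 (rank 1873). Erythroid and megakaryocyte genes had 11 of 19 (adjusted permutation p = 0.37), with a promoter peak at Tal1 (rank 906). Cardiac muscle genes, another setting of GATA4, had 5 of 15 (adjusted permutation p = 0.99), including an intron of Tbx5 (rank 876). Neuron genes had 5 of 18, at the lower end of the central 95% of random lists (5 to 13) but inside it. Lists with fewer than 5 made up 0.75% of the random lists, a share that leaves out ties. The neuron count fell below the central 95% with summits within 5 kb of a start site (1, range 2 to 10). It was also below by nearest start site (2, range 4 to 12), and inside under the other alternatives. Coagulation and complement genes had 16 of 23 (adjusted permutation p = 0.098), led by an intron of Masp1 (rank 403). This list passed the threshold with the conservative list, at 10 genes (adjusted permutation p = 0.0366), and with random lists without matching, at 16 (adjusted permutation p = 0.0418). It also passed under settings chosen after seeing the data: 11 genes with summits outside promoters with WGATAR (adjusted permutation p = 0.0264), and 17 with the later run's list (adjusted permutation p = 0.04).

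**Figure D1:**
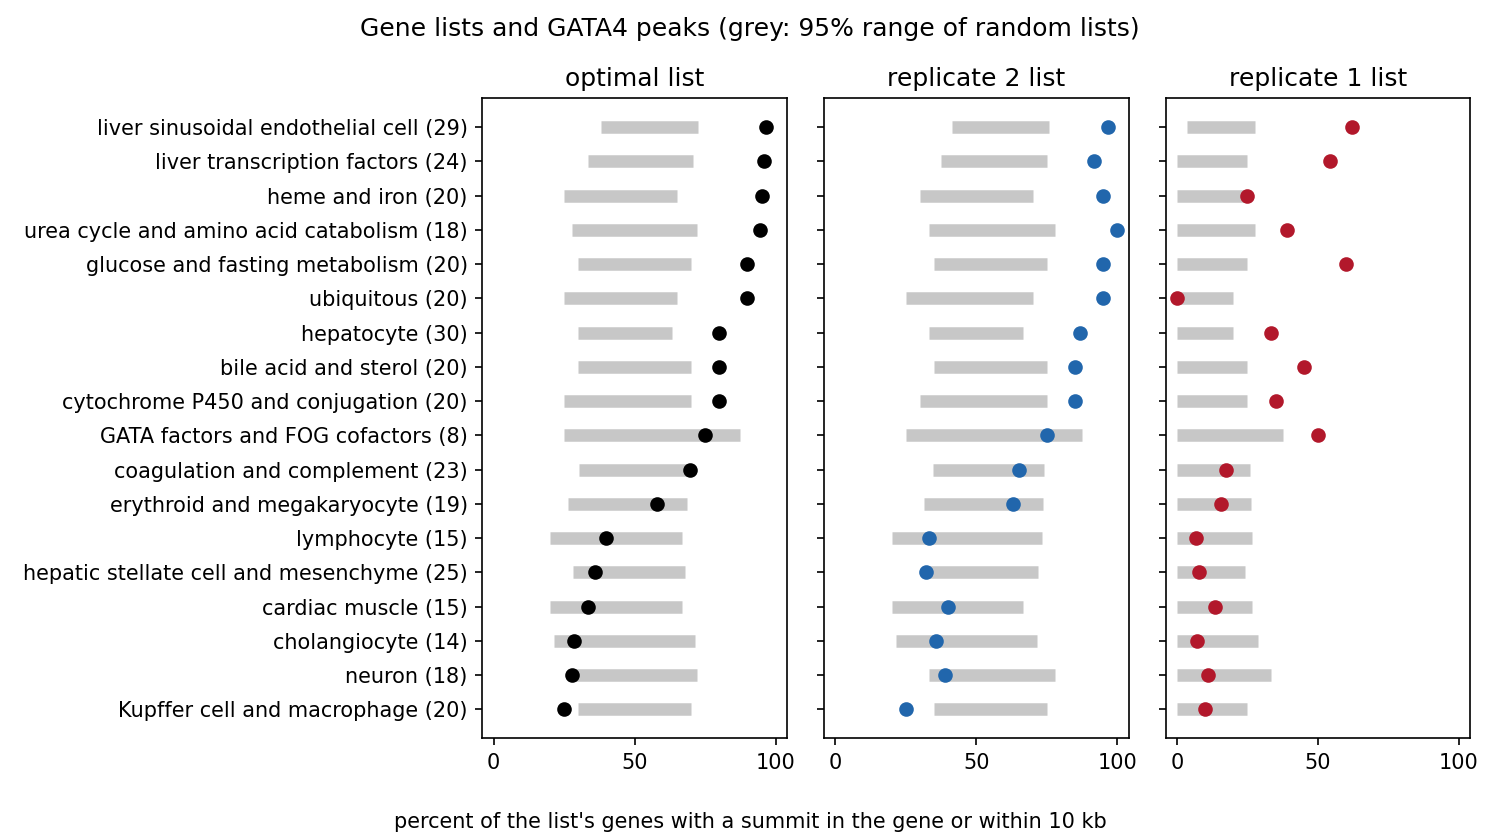
Percent of each list's genes with a summit in the gene or within 10 kb (x axis) for 18 gene lists (y axis, number of genes in brackets), in the optimal list and in each replicate's own list. Points are the observed percentages and grey bars the central 95% of 10000 random lists matched on gene span. Endothelial genes lie above the bar in all 3 panels, whereas ubiquitous genes lie above it in the optimal and replicate 2 panels and at 0 in the replicate 1 panel.

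Ubiquitous genes, fixed as a background list, had a summit near 18 of 20 members in the optimal list (adjusted permutation p = 0.00036) and near 19 in replicate 2's list. Replicate 1's list reached 0 of them, against a mean of 1.61 in random lists, and the conservative list 4. The strongest peak of this list lay at the promoter of Psmb2 (rank 2706). The call for ubiquitous genes rested on replicate 2 and on promoter peaks: with summits outside promoters alone, a setting chosen after seeing the data, 8 of 20 had one (adjusted permutation p = 0.18). The endothelial list kept 26 of 29 and the hepatocyte list 19 of 30 under that setting, both past the threshold (adjusted permutation p = 0.00036).

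Among genes of the GATA family and their FOG cofactors, 6 of 8 had a summit (adjusted permutation p = 0.37). Zfpm1, which encodes FOG1, had 18 summits in the gene or within 10 kb, on chromosome 8 at 122282141 to 122337251. The strongest of these lay in an intron (rank 97). Gata4 itself, on chromosome 14 at 63198922 to 63271692, had 12, the strongest in an intron (rank 3131). Gata2 had 4, Zfpm2 4, Gata6 2 and Gata3 1, whereas Gata1 and Gata5 had none. In replicate 1's list 4 of the 8 genes had a summit (adjusted permutation p = 0.038).

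The peak of rank 1 in the optimal list lay on chromosome 2 at 128967056 to 128967395, 175 bp from a start site of Zc3h6, and had no WGATAR within 50 bp of its summit. Introns of Rhobtb1, Map3k3 and Pdlim5 held the peaks of rank 2, 4 and 6. The promoter of Pzp, which encodes a plasma protease inhibitor, held that of rank 5, an exon of Tuba4a that of rank 7, and introns of St3gal4 and Vwa7 those of rank 8 and 9. The peak of rank 10 lay 687 bp from a start site of Slc25a23 and inside Crb3. These peaks were in both replicates' lists. Further promoter peaks among the 10 strongest at promoters lay at Sulf1, BC003965, Atg4d, Atf3, Sde2, Lyl1 and Got1, of which Sde2's was missing from replicate 1's list.

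GATA motifs marked the peaks. WGATAR occurred within 50 bp of 52.8% of the summits of the optimal list (12697 of 24050, 52.2 to 53.4%), against 16.0% of windows of the same length at 500 bp to each side. The excess was 3.30-fold, and the two-sided Fisher's exact p was below what double precision can represent. The stricter AGATAA occurred at 27.2% of summits and 5.39% of flanks. The share fell with the authors' signal, from 76.1% in the quintile of strongest signal to 32.7% in the weakest. In the replicates' own lists WGATAR occurred at 67.3% (replicate 1) and 49.1% (replicate 2) of summits.

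Some motifs of other factor families were also more frequent at summits than in flanks. MGGAAR, the core of ETS factor sites, where M is A or C, occurred at 46.0% of summits and 25.6% of flanks. The hormone receptor hexamer AGGTCA occurred at 11.8% and 6.27% (adjusted p = 9.88e-138, Fisher's exact test over 19 motifs). The E-box CAGCTG, of the kind bound by TAL1, occurred at 7.68% and 4.68% (Fisher's exact test, adjusted p = 2.29e-57). The HNF4 motif CAAAGTYCA, where Y is C or T, was rare, at 0.973% of summits and 0.289% of flanks (Fisher's exact test, adjusted p = 6.5e-31). The motif searched for FOX factors, TRTTKRY, where K is G or T, was at 21.7% of all summits and 21.6% of flanks (Fisher's exact test, adjusted p = 0.718). This short motif was common in flanks, so like shares do not show a lack of FOX sites. It was lower at promoter summits than in their flanks, at 10.5% against 15.8% (Fisher's exact test, adjusted p = 2.34e-19), and higher at other summits, at 24.8% against 23.1% (Fisher's exact test, adjusted p = 2.85e-05). The unrelated control WTATGC was lower at summits, at 3.89% against 6.05% (Fisher's exact test, adjusted p = 2.21e-35). Summits exceeded their flanks in GC content by 9.52 points at promoters and by 3.50 elsewhere. Base composition was thus not held equal in these comparisons with flanks or in those by position below.

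Summits concentrated at promoters. Of the optimal list, 21.6% (21.1 to 22.1%) lay within 1 kb of a transcription start site, against a mean of 2.19% and a highest value of 2.41% in 100 shuffles within chromosomes. Introns held 40.4%, against 37.6% in shuffles, and intergenic sequence 35.6%, against 57.6%. The median distance to the nearest start site was 15569 bp, against 60465 bp in shuffles. The promoter share was 7.77% in replicate 1's list, 25.2% in replicate 2's and 10.4% in the conservative list, all above every shuffle.

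**Figure D2:**
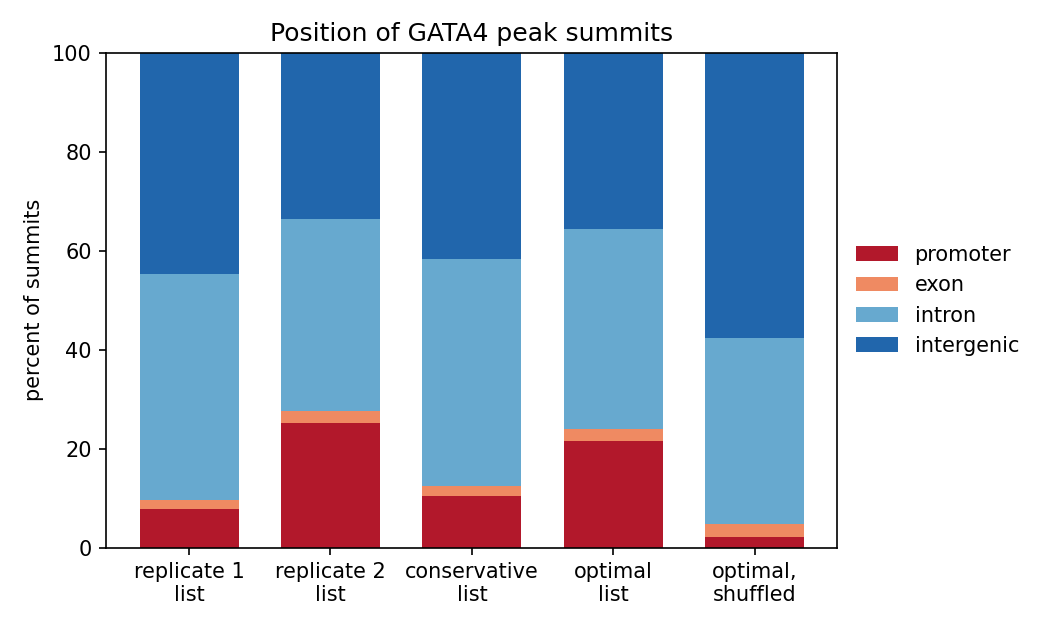
Percent of summits (y axis) at promoters within 1 kb of a start site, in exons, in introns and in intergenic sequence, for each peak list and for the mean of 100 shuffles of the optimal list (x axis). The promoter share is 7.77% in replicate 1's list and 25.2% in replicate 2's, against 2.19% in the shuffles.

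Promoter peaks carried the GATA motif less often than other peaks. WGATAR lay within 50 bp of 25.7% (24.5 to 26.9%) of promoter summits, 61.3% (60.4 to 62.3%) of intronic summits and 59.4% (58.3 to 60.4%) of intergenic ones. Promoter summits had a mean GC content of 61.9% and other summits one of 48.6%. Among promoter and other peaks of like GC, a comparison chosen after seeing the data, the gap was 8.98 percentage points (95% bootstrap interval 7.04 to 11.02). This GC was taken in the window searched, so the motif itself entered the match. With GC from 50 to 100 bp beside the summit the gap was 18.1 points (15.7 to 20.3). The SP motif GGGCGG was at 30.4% of promoter summits, against 11.8% of their flanks, and at 3.52% of other summits, against 1.72%. MGGAAR was at 42.3% of promoter summits, against 25.7%, and at 47.0% of other summits, against 25.6%. AGGTCA was at 13.5% of summits outside promoters, against 6.57% of their flanks, and at 5.64% of promoter summits, against 5.20% (adjusted p = 0.308, Fisher's exact test). In replicate 1's list, promoter summits had WGATAR at 63.7% (58.4 to 68.6%) and other summits at 67.6%. In replicate 2's list they had it at 20.9% and 58.7%.

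**Figure D3:**
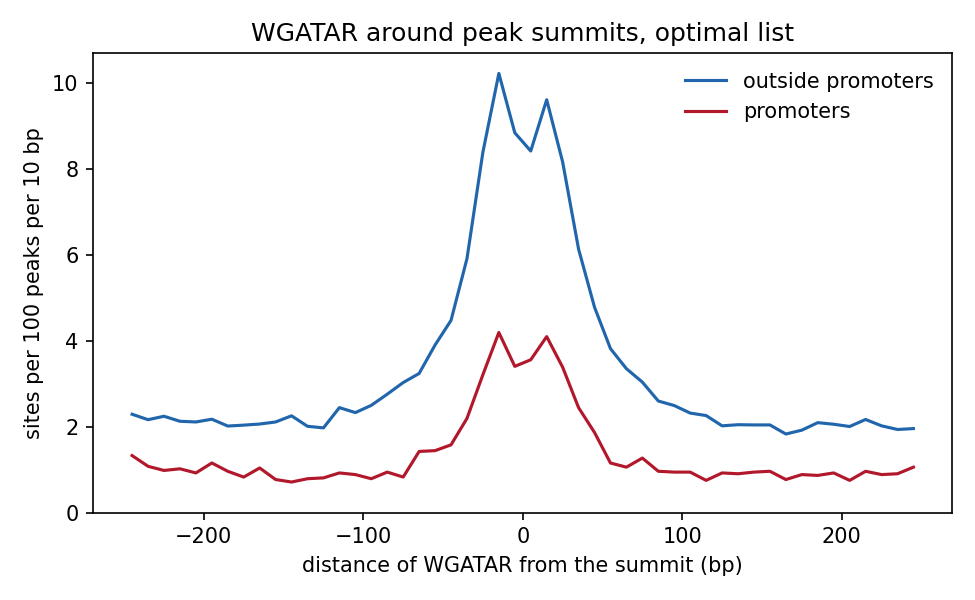
Number of WGATAR sites per 100 peaks in each 10 bp (y axis) by distance from the summit in bp (x axis), for promoter peaks and other peaks of the optimal list. Both curves rise around the summit, and that of promoter peaks stays lower.

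**Figure D4:**
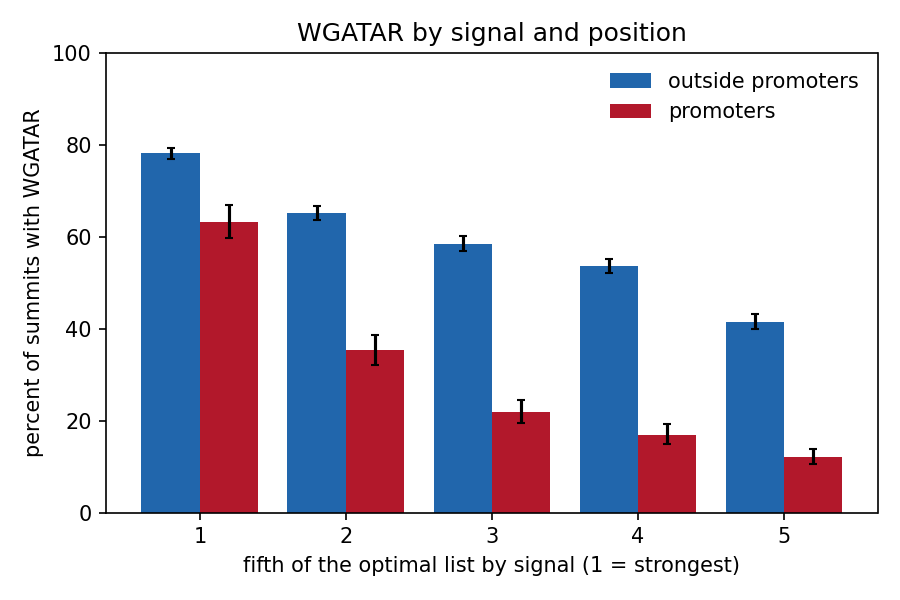
Percent of summits with WGATAR within 50 bp (y axis) in quintiles of the optimal list ranked by signal (x axis), for promoter peaks and other peaks, with 95% Wilson intervals. In the strongest quintile the shares are 63.3% and 78.2%, and in the weakest 12.1% and 41.5%.

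Most of replicate 1's peaks lay in replicate 2's longer list. Of replicate 1's 4287 peaks, 92.0% (91.2 to 92.8%) shared at least 1 base with a peak of replicate 2, against at most 0.980% in 100 shuffles. Of replicate 2's 26314 peaks, 15.1% (14.7 to 15.5%) shared a base with one of replicate 1, against at most 0.171%. Replicate 2 had 6.14 times as many peaks. When the 4287 strongest peaks of each replicate's relaxed list were compared, 57.7% (56.2 to 59.2%) of replicate 1's overlapped those of replicate 2, and of the 1000 strongest 48.8% did. Across the 52722 peaks of the authors' list ranked between the replicates, Spearman's rho of the 2 signals was 0.47. Between the 2 inputs of replicate 1's own ranked list rho was 0.28, and between those of replicate 2's it was 0.62. The lists hold different peaks. These are correlations across peaks, which are not independent. Shared peaks carried WGATAR more often than peaks of 1 replicate alone. In replicate 1 the shares were 69.0% and 47.8% (two-sided Fisher's exact p = 9.61e-15), and in replicate 2 they were 74.9% and 44.6% (p = 2.32e-281). Signal was not matched in these comparisons. Of the optimal list's strongest quintile 60.0% overlapped replicate 1's list, and of its weakest 3.08%. WGATAR fell from 76.1% to 32.7% between the same quintiles. The peaks of replicate 2 alone still exceeded their flanks by 29.6 percentage points.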

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

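Both of the following values come from data outside the comparisons above. The optimal list held 33 peaks outside chromosomes 1 to 19, X and Y, 11 of them on the mitochondrial genome. In the archived mm9 lists, 4409 of the 4811 peaks of the SPP list (91.6%) shared a base with a peak of the MACS2 list, and 4371 of the 5867 MACS2 peaks (74.5%) with one of the SPP list.

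Of the tests in the next paragraphs, those of promoter peaks alone in replicate 2, of the promoter share at equal length, of peaks of like GC and of the ubiquitous genes were chosen only after the result was seen. No biological explanation was tested for these 3 patterns, because the design has 1 group.

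Replicate 2 had 26314 thresholded peaks and replicate 1 had 4287. Of replicate 2's peaks, 22341 were absent from replicate 1 and carried WGATAR 29.6 percentage points above their flanks. This argues against background as the source of all of them. Replicate 2's shared peaks exceeded their flanks by 56.7 points, so background among part of the 22341 stays open. The 6312 of the 22341 at promoters had an excess of 7.12 points (95% bootstrap interval 5.99 to 8.20). This lay between the 2 points allowed for background and the 10 points first set as the bound against it. That bound was lowered to 2 after this value was seen, so the test cannot decide. Background called as promoter peaks in replicate 2 stays open. Weaker signal in replicate 1 at the same sites may account for part of the difference. Of the peaks of replicate 2 alone, 22.4% overlapped the equally many strongest relaxed peaks of replicate 1, against at most 0.806% in shuffles. Any relaxed peak of replicate 1 was overlapped by 54.4%, against at most 8.46% in 20 shuffles. The shuffles did not keep the concentration of peaks at promoters, so an excess over them is not particular to this explanation. Promoters made up 8.43 points more of the 4287 strongest relaxed peaks in replicate 2 (16.5%, 15.4 to 17.7%) than in replicate 1 (8.09%, 7.32 to 8.95%). That is beyond the 2 points allowed for a weaker library with the same order of sites. But each relaxed list, from the earlier run, used a control file of its own. In these lists a different order of sites thus cannot be told apart from the different controls. The later run's ranked lists, each with both control files, were not compared at equal length. This explanation stays open.

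Promoter peaks of the optimal list carried WGATAR at 25.7% and other peaks at 60.3%. The gap was narrow in replicate 1's list (63.7% and 67.6%) and in replicate 2's shared peaks (68.0% and 75.5%). It was wide in the peaks of replicate 2 alone (18.4% and 54.9%). Lower signal at promoters is argued against as the whole cause in the optimal list. The gap within its quintiles of signal averaged 29.5 points and was at least 14.9 points in each. GC content is also argued against as the whole cause, but matching on it narrowed the gap: among peaks of like GC within 50 bp of the summit the gap fell from 34.6 to 8.98 points (95% bootstrap interval 7.04 to 11.02), and with GC taken beside that window to 18.1 (15.7 to 20.3). Signal and GC together stay open, since the gap matched on both was 6.37 points (4.58 to 8.20) and its interval held the bound of 5. That match took GC in the window searched, so the motif itself entered it. Other base composition cannot be told apart with the flanks: the summit share was 2.27 times the flank share at promoters and 3.48 times elsewhere, but summits exceeded their flanks in GC by 9.52 points at promoters and by 3.50 elsewhere, which itself lowers that ratio. Recruitment without a GATA site and antibody-independent enrichment of open promoters both stay open and were not tested.

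Ubiquitous genes had peaks near 19 of 20 members in replicate 2's list and 0 in replicate 1's. Promoter peaks may account for this count, but the values here are from the optimal list and not from the replicates' own lists. Of the ubiquitous genes 17 had a promoter peak in the optimal list, and in 3 of them one had WGATAR. Outside promoters, 5 of the 20 were near a summit with WGATAR, no more than the 7 at the upper end of the central 95% of random lists. With or without WGATAR, 8 of the 20 were near a summit outside promoters (adjusted permutation p = 0.18). The call was thus lost without promoter peaks alone, so the test cannot decide whether the missing motif matters. A difference in depth or in the yield of the immunoprecipitation stays open, since neither is known here.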

How the results depend on the processing

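The equal-length comparison at the larger number of peaks, the settings with promoter peaks alone or without them and those with the later run's list were chosen only after the result was seen. The enrichment of WGATAR kept its direction and passed the threshold under all 9 alternatives, and promoters lay above every shuffle under all 6. Without one replicate, WGATAR was at 49.1 to 67.3% of summits and promoters held 7.77 to 25.2%. Overlap moved with its definition. Of replicate 1's peaks, 70.1% overlapped under a reciprocal overlap of 50%, 85.2% with summits at most 100 bp apart and 94.3% at an IDR of at most 0.01. For replicate 2 the values were 11.4%, 13.9% and 15.8%. The equal-length overlap was 48.8% for 1000 peaks, 51.9% for 10000 and 35.6% for 26314. Spearman's rank correlation between the replicates' signals was 0.44 past the threshold only. The cause of these shifts was not tested. The number of gene lists past the threshold stayed between 8 and 10. Of 162 comparisons of a gene list under an alternative, 140 kept the direction against the random mean and the side of the threshold, 5 lost the call and 5 gained it, in a one-sided test for high counts. Coagulation and complement genes gained it in 4 of the 9 alternatives. The other 12 changed sides of the random mean. Of these the ubiquitous list had 0 of 20 genes without replicate 2, inside the central 95% of random lists (0 to 4), and 19 without replicate 1. So the call was lost, in a list with fewer peaks. The other 11 missed the threshold in the main run and here, and went from below the mean to above it: stellate 10 and cardiac 6 genes by nearest start site, lymphocyte 3 with the conservative list, cardiac 2 without replicate 2 (6 without replicate 1), stellate 9, lymphocyte 5 and cardiac 5 outside promoters, and stellate 6, cholangiocyte 3, lymphocyte 4 and cardiac 4 outside promoters with WGATAR. The cause of these was not tested. Depth is unknown, so a peak absent from replicate 1's list is not shown to be absent from that library.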

Other observations

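Among genes of at most 100000 bp, a rule chosen after the values were seen, Zfpm1 had the most summits in the gene or within 10 kb, at 18. Kdr, which encodes the main endothelial receptor for vascular endothelial growth factor, had 13 on chromosome 5 at 75932827 to 75978458, and Cuedc1 and Sh3bp5 also had 13. Epas1, Gata4 and Itpkb had 12 each. Few summits lay in repeats: 8.28% were in soft-masked sequence, against 32.9 to 33.9% in 20 shuffles. The shuffles left out assembly gaps only. Peaks missing from repeats because reads cannot be placed there were not told apart from absent binding. CTG followed by a gap and WGATAA, the arrangement of an E-box beside a GATA site, occurred most often with a gap of 8 bp, within 100 bp of 487 summits, against 326 to 450 for the other gaps of 0 to 20 bp. This spacing was not tested.

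Peaks lay near genes of 2 cell types, the sinusoidal endothelium and the hepatocyte, and a hypothesis was that their partner motifs differ. The bounds for 3 motifs were set before these values were computed. MGGAAR, the ETS core, was at 66.9% (59.6 to 73.4%) of 175 summits near endothelial genes and at 29.4% (24.0 to 35.4%) of 245 near hepatocyte and metabolic genes, a difference of 37.5 percentage points (two-sided Fisher's exact p = 2.22e-14, adjusted p = 6.67e-14 over 3 motifs). Averaged per gene, the shares were 68.3% ± 22.2 (SD, n = 28 genes) and 27.8% ± 32.4 (SD, n = 97 genes), with a two-sided permutation p = 1e-05, the smallest that 100000 permutations can give. In their flanks the shares were 27.7% and 22.9%, and among peaks also in replicate 1's list they were 68.9% and 29.5%. Among summits with WGATAR the shares were 61.2% of 85 and 25% of 152, a difference of 36.2 points (Fisher's exact p = 7.06e-08), a test chosen only after the result was seen. Among summits without WGATAR they were 72.2% of 90 and 36.6% of 93, a difference of 35.7 points. The difference was thus of like size with and without a GATA motif in the same window, so the values do not tie it to GATA sites. Over the whole optimal list MGGAAR was at 44.0% of summits with WGATAR and 48.2% of those without. Whole liver holds both cell types and the peaks carry no cell label, so a difference in partner motifs remains a hypothesis. Open chromatin of endothelial cells that is rich in ETS sites was not tested apart from it.

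The other 2 motifs went differently. AGGTCA was 2.53 points less frequent near endothelial genes, a change of -2.53 points that did not pass the test (Fisher's exact p = 0.438), so a difference in hormone receptor sites cannot be told apart from none with these numbers of summits. More GATA sites near endothelial genes, the third hypothesis, is argued against: WGATAR was at 48.6% of summits near endothelial genes and at 62.0% near hepatocyte genes, a difference of -13.5 points (Fisher's exact p = 0.00704, adjusted p = 0.0106). Averaged per gene the difference was -19.0 points (permutation p = 0.011). Among peaks also in replicate 1's list the shares were 77.8% of 45 and 80.3% of 61 (Fisher's exact p = 0.811). These summits are too few to tell whether the difference holds in that list or rests on peaks outside it.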
